A study of Homo sapiens with 2 samples.

How the data were processed

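Nuclear RNA was measured by droplet single-nucleus RNA sequencing in grafts of human brain organoids derived from H9, an established human embryonic stem cell line. The organoids had been grafted into the primary visual cortex of immunodeficient mice, and the grafts were collected 150 days after transplantation. The labels name 2 groups, Non-Target and Target neuromodulation, with 1 library each. What separates the neuromodulation settings is not given in the sources used here.

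The deposited values are UMI counts per gene and barcode, not normalised. Reads were checked with FastQC 0.11.2 and counted with Cell Ranger, version 7.0 per the submitters' processing notes and 7.2.0 per the file headers. Seurat 4.1.1 is named in the submitters' processing notes without a stated role. The same notes name both GRCh38 and GRCm39, the human and mouse genome builds, while the feature list holds human genes only. How mouse reads were separated is not given in the sources used here, so RNA of host cells that maps to human genes can be in these counts. The lowest total of a deposited barcode was 500 UMIs in both libraries, and the rule behind that floor is not given in the sources used here. Gene positions are from GENCODE v29 on GRCh38, matched by Ensembl identifier for 94.6% of the identifiers. Whether the counting used strand is not given in the sources used here.

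The files hold 2799 barcodes for the Non-Target library and 5969 for the Target library, where the labels state about 18000 nuclei loaded per sample. Nuclei with at least 500 genes and at most 5% mitochondrial UMIs were kept. This left out 428 barcodes (15.3%) of the Non-Target library and 977 (16.4%) of the Target library, and 2371 and 4992 nuclei remained. Scrublet as provided in scanpy, run per library with an expected doublet rate of 6%, called 6 Non-Target nuclei and 4 Target nuclei, or 0.253% and 0.0801%. A caller that marks so few has not worked, so doublets must be taken as still present, although the calls were removed. The analysed set was 2365 Non-Target and 4988 Target nuclei.

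Counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes were scaled to at most 10 SD, and 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1. Both libraries were clustered together without integration, which gave 17 clusters. Of 26 marker lists, those for cell classes and broad neuron types named the clusters, and those for ventral neuron origins and cortical layers did not. A cluster took the class whose markers had the highest mean log2 ratio against all other nuclei, with choroid plexus left out of this step. That mean had to reach 1, with at least 3 markers seen in 10% of the nuclei and at 2-fold or more. Clusters short of this that kept choroid plexus markers, with a mean log2 ratio to all nuclei of at least -0.5 and at least 3 markers in 10% of nuclei, were called choroid plexus-like unless other classes had more markers among the 10 leading genes. Clusters led by at least 3 ribosomal protein or mitochondrial genes, with classes tied within 0.25, or led by pigment or adipose genes stayed unnamed. The same held for clusters with low median UMIs and no marker of their best class among the leading genes. The markers were fixed beforehand, whereas these naming thresholds and the pigment and adipose lists were set after the clusters had been seen. They kept 354 Non-Target nuclei (15.0%) and 393 Target nuclei (7.88%) out of any class.

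With 1 library per group no test was made and no p-value is given. Shares of nuclei have exact Clopper-Pearson 95% intervals and differences of shares have Newcombe intervals. UMIs were summed per class and library and given as CPM (UMIs of the gene over all UMIs of the class and library, scaled as usual for this unit) with exact Poisson intervals, and ratios have exact intervals conditional on the summed count. All intervals cover counting error only. A count of 0 was set at a floor of 3 UMIs over the class to give a ratio, which is not the lower limit of its exact interval. Log2 ratios had 0.5 UMI added to each sum. Classes with at least 100 nuclei in both libraries were compared, and the neuron-like class was the main one because no excitatory class was found in the main setting.

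The named genes follow a rule. In the main class they are the 12 highest and 12 lowest CPM ratios among genes with at least 100 UMIs over both libraries, and in the other classes the 5 highest and 5 lowest. Clone-named and LINC genes, mitochondrial and ribosomal protein genes, and genes that mark sex were left out of the ranking. The rule also names 2 members at each end of every list described and the markers of the layer lists. Some genes that the rule names are left out of this text. Gene names outside this rule were chosen after their values were seen, among them HTR2C, TTR and the genes compared between the neuron-like clusters. For 23 gene lists the median log2 ratio of members with at least 20 UMIs was set against 10000 random lists of the same size matched on expression in 20 bins, as a description of these libraries. Lists with under 3 such members got no value. The samples, filters, markers, lists, naming of genes and most alternatives were chosen before the data were examined. A further list of 35 interferon response genes was written after IFI6, IFI44L and B2M had been seen to be high in the Target library.

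The ratio and list steps were tested on simulated counts with 200 changed genes. At the size of the choroid plexus-like class, with 12962 genes, 95.8% of the intervals held the true ratio and 4 of 50 unchanged lists lay outside the central 95% of random lists. At the size of the neuron-like class, with 1175 genes, these values were 94.9% and 0 of 50. In both simulations 100% of the changed genes came out on the right side.

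The alternatives were no filter, a stricter filter (1000 genes, 2% mitochondrial UMIs), doublet calls kept, resolutions 0.5 and 2, 4000 variable genes, scaling within each library, 5 other seeds, thinning of every nucleus to 1700 UMIs, other totals and size factors, the mean of each nucleus's CPM, list minimums of 5 and 100 UMIs, and list means. Thinning left out 588 Non-Target and 1004 Target nuclei. Added after the data had been seen were removal of the highest doublet scores (0.8% of nuclei for each 1000 barcodes), equal weight for the choroid plexus-like clusters, the neuron-like class without its Cajal-Retzius-like cluster, the joint share of the choroid plexus-like and unnamed clusters that keep choroid plexus markers, and in the main setting the share of every cluster that keeps them. The analysis used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9.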

Results

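Nuclei were profiled from grafts of human brain organoids in mouse primary visual cortex, 1 library after Non-Target and 1 after Target neuromodulation, 150 days after transplantation. The Non-Target library held 9376568 UMIs in 2799 barcodes and the Target library 26511563 UMIs in 5969 barcodes. After filtering, 2365 Non-Target nuclei had a median of 2903 UMIs and 1726 genes, and 4988 Target nuclei a median of 3286.5 UMIs and 1858 genes. Mitochondrial UMIs made up a median of 0.329% and 0.563%. Each group is 1 library, so no difference has a replicate check, and all intervals cover counting error only.

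The first comparison asked which cell classes the grafts held. Choroid plexus-like nuclei, the epithelial type that secretes cerebrospinal fluid, were the largest class in both libraries. They were 70.5% of Non-Target nuclei (95% interval 68.6 to 72.4, n = 1668) and 50.2% of Target nuclei (48.8 to 51.6, n = 2504). Fibroblast-like nuclei were 16.1% of the Target library (15.1 to 17.1, n = 802) and 0.169% of the Non-Target library (0.0461 to 0.432, n = 4). Glial classes were also higher in the Target library. OPC-like nuclei, which resemble oligodendrocyte precursor cells, were 5.35% against 0.973%, and astroglia-like nuclei were 3.01% against 0.550%.

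Neuron-like nuclei were few in both libraries, at 5.54% of Non-Target nuclei (4.65 to 6.54, n = 131) and 3.05% of Target nuclei (2.59 to 3.56, n = 152). The difference of -2.49 percentage points was 0.0101 with nuclei thinned to 1 depth and -8.01 at resolution 0.5. Thinning left out nuclei with fewer than 1700 UMIs. Neuron-like nuclei had medians of 894 Non-Target and 797 Target UMIs, so most of the class was lost there. The thinned value therefore does not show whether depth set the difference. Ependymal-like nuclei, with genes of motile cilia, were 6.47% of the Non-Target and 11.5% of the Target library. They carried HTR2C, a serotonin receptor gene abundant in choroid plexus, at 38224 and 40725 CPM, near the 41786 and 48080 CPM of choroid plexus-like nuclei. Cycling-cell-like nuclei were 0.803% and 2.91%. Neuron-like, OPC-like, astroglia-like and cycling-cell-like nuclei together made up 7.86% of the Non-Target library (6.81 to 9.02) and 14.3% of the Target library (13.4 to 15.3). This sum takes in the cycling-cell-like cluster, which kept choroid plexus markers. It leaves out an unnamed cluster led by neuronal genes, described next, whose share was higher in the Non-Target library. The contrast in the sum thus depends on the naming rule. Clusters without a name held 354 Non-Target nuclei (14.97%) and 393 Target nuclei (7.88%), and among them a cluster led by neuronal genes such as GRIA2 and SNAP25 had 200 and 126 nuclei (8.46% and 2.53%) and a cluster led by adipose genes 0 and 64. The fibroblast-like, OPC-like, astroglia-like and adipose-gene clusters came mostly from 1 library and cannot be separated from that library.

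The choroid plexus-like share depended on which clusters met the naming rule, and its difference of -20.3 percentage points became 5.15 with clustering seed 4. Counting the choroid plexus-like clusters with the unnamed clusters that kept choroid plexus markers, a choice made after the data had been seen, gave 85.5% of Non-Target nuclei (84.0 to 86.9) and 56.8% of Target nuclei (55.4 to 58.2). This count takes in unnamed clusters led by neuronal genes (200 and 126 nuclei), pigment genes (101 and 77) and ribosomal protein genes (32 and 72) and a cluster tied between classes (21 and 54). It gave a difference between -22.5 and -31.0 points in the alternatives run for shares. With the ependymal-like and cycling-cell-like clusters, which kept these markers too, it was 92.8% of Non-Target nuclei (91.7 to 93.8) and 71.2% of Target nuclei (70.0 to 72.5).

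**Figure D1:**
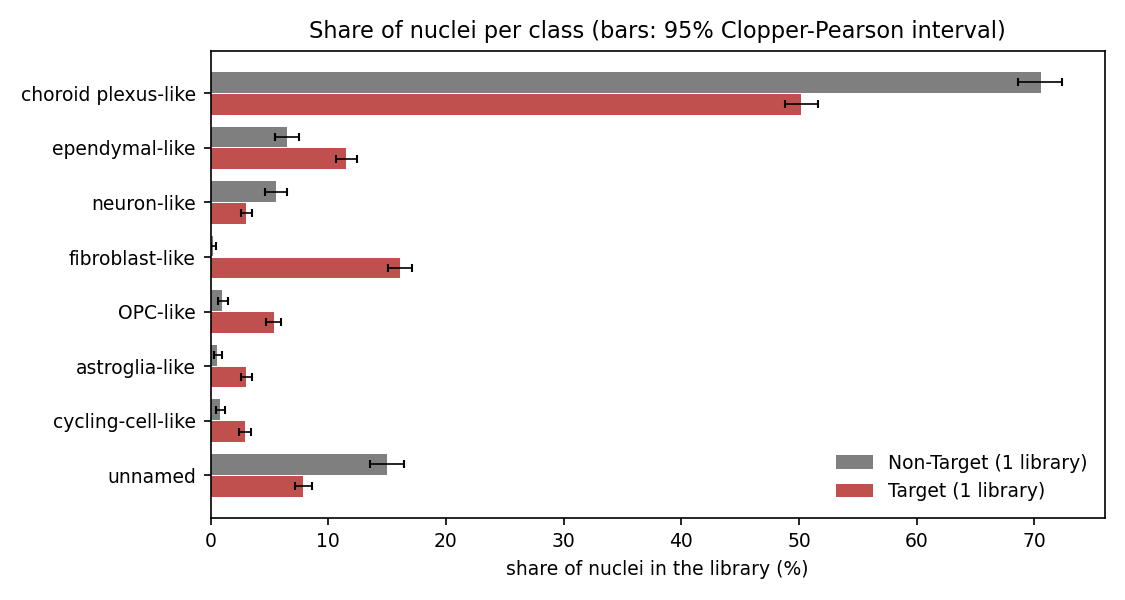
Share of nuclei per class in percent of the library, for the Non-Target (grey) and Target (red) library; error bars are 95% Clopper-Pearson intervals and cover counting error only. Choroid plexus-like nuclei were 70.5% and 50.2%, and fibroblast-like nuclei 0.169% and 16.1%.

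Free RNA was measurable in both libraries. TTR, the transthyretin gene of choroid plexus epithelium, was at 2257 CPM in Non-Target choroid plexus-like and 2712 CPM in neuron-like nuclei. It stood at 4806 CPM in Target choroid plexus-like nuclei and at 5727 CPM in neuron-like, 5090 CPM in fibroblast-like and 4919 CPM in OPC-like nuclei of that library. HTR2C differed between Target classes, from 4651 CPM in neuron-like nuclei to 48080 CPM in choroid plexus-like nuclei.

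The second comparison asked about cortical layer identity, which the series title raises. No cluster met the rule for excitatory neurons in the main setting, so layer shares among excitatory neurons were not computed, and layer markers are given for neuron-like nuclei. That class joined a shallow cluster (110 Non-Target and 96 Target nuclei) and a Cajal-Retzius-like cluster (21 and 56). Whether the shallow cluster is human is not settled, and the Cajal-Retzius-like cluster supplied most of the Target UMIs. The layer values are sums over the class, so a change of this mix is not told apart from a change within a cluster. SLC17A7, the vesicular glutamate transporter of cortical excitatory neurons, had 2 UMIs in each library. Among deep-layer markers, BCL11B was at 304 CPM in the Non-Target library (238 to 382) and 123 CPM in the Target library (89.4 to 164), TLE4 at 166 and 81.7 CPM, and ETV1 at 104 and 43.6 CPM. TBR1 was at 79.0 and 49.0 CPM, FOXP2 at 87.3 and 76.3 CPM, LDB2 at 183 and 144 CPM, and HS3ST4 at 62.4 and 46.3 CPM. SOX5 was higher in the Target library, at 204 CPM (151 to 269) against 371 CPM (311 to 438), and ZFPM2 was at 312 CPM (245 to 391) and 376 CPM (316 to 444). FEZF2 had 4 and 11 UMIs, SYT6 had 2 and 1, and CRYM had 0 and 2.

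Of the upper-layer markers, CUX1 was at 337 and 229 CPM, CUX2 at 212 and 174 CPM, GLIS3 at 566 and 191 CPM, and RASGRF2 at 133 and 65.4 CPM in the Non-Target and Target libraries. CALB1 had 13 and 1 UMIs, POU3F2 had 1 and 7, and LAMP5 had 1 and 0. Of the layer 4 markers, UNC5D was at 869 CPM (755 to 995) and 1098 CPM (993 to 1211), RORB at 74.9 and 106 CPM, NTNG1 at 553 and 357 CPM, and KCNH5 at 116 and 131 CPM. PLCXD2 had 4 and 5 UMIs, and RSPO1 had 0 in both. The subplate marker NR4A2 had 36 UMIs in the Non-Target and 1 in the Target library, and ST18 had 27 and 9. CCN2 had 3 and 11 UMIs, KCNAB1 had 1 and 1, CPLX3 had 0 and 1, and NXPH4 had 0 and 1. Several of these genes were not specific to neurons here. CUX2 was at 521 CPM in Non-Target and 554 CPM in Target choroid plexus-like nuclei, above its level in neuron-like nuclei. Of all CUX2 UMIs, 70.2% were in choroid plexus-like nuclei and 0.746% in neuron-like nuclei, shares that also reflect how many UMIs each class holds.

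The third comparison was expression within neuron-like nuclei, with 240439 Non-Target and 367035 Target UMIs. CNTNAP2 and ADARB2 were among the genes higher in the Target library, and ZBTB20 and ZEB2 among those lower. CNTNAP2, a neurexin-family adhesion gene (chromosome 7, 146116002 to 148420998), was at 578 CPM (486 to 683) and 3539 CPM (3349 to 3737), 6.12-fold higher (5.14 to 7.35). ADARB2, at 187 and 1052 CPM, was 5.62-fold higher, and the kainate receptor gene GRIK1 5.32-fold. Also among the 12 highest were LHFPL3, ZNF385D, CNTNAP4, CDH13, LUZP2, SPOCK3, CHL1 and SLC35F1, between 4.80-fold and 7.98-fold higher.

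Among the 12 lowest, ZBTB20 was at 2325 CPM in the Non-Target and 526 CPM in the Target library, 4.42-fold lower (3.75 to 5.23), ZEB2 at 1984 and 523 CPM, 3.79-fold lower (3.20 to 4.51), and ZBTB18 at 387 and 81.7 CPM, 4.73-fold lower. CAMTA2 was 5.07-fold lower (3.21 to 8.27), and EPHA4, an ephrin receptor gene, 3.96-fold lower. SYT7, MBD6, PRLR, CCNL1, C6orf62 and VAT1L were between 3.58-fold and 4.20-fold lower. PCAT1, annotated as antisense, was 4.58-fold lower, and its reads are uncertain because strand use is not given.

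The class joined 2 clusters of different make-up. A shallow cluster of 110 Non-Target and 96 Target nuclei (median 752.5 UMIs) supplied most of the class's nuclei in both libraries. A Cajal-Retzius-like cluster of 21 and 56 nuclei (median 4658 UMIs) supplied most of the Target UMIs. In the shallow cluster clone-named and LINC RNAs, mostly absent from mouse, were 2.45% of UMIs, against 4.03% to 5.39% in the other clusters. Within the Cajal-Retzius-like cluster CNTNAP2 was at 1213 and 4359 CPM, 3.59-fold higher (2.96 to 4.39), and ADARB2 at 42.6 and 1269 CPM, while RELN, its marker, was at 21289 and 9097 CPM. ADARB2 is also on the marker list for interneurons of the caudal ganglionic eminence. A different mix of neuron types in this cluster is therefore not told apart from a change within 1 type. Within the shallow cluster the 12 lowest genes of the class were all lower in the Target library, from MBD6, 1.36-fold, to VAT1L, 6.89-fold, and the intervals of MBD6 and C6orf62 reached 1. Within the Cajal-Retzius-like cluster ZEB2, EPHA4, PRLR, PCAT1, CCNL1, SYT7 and VAT1L had ratios above 1, all with intervals that span 1.

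**Figure D2:**
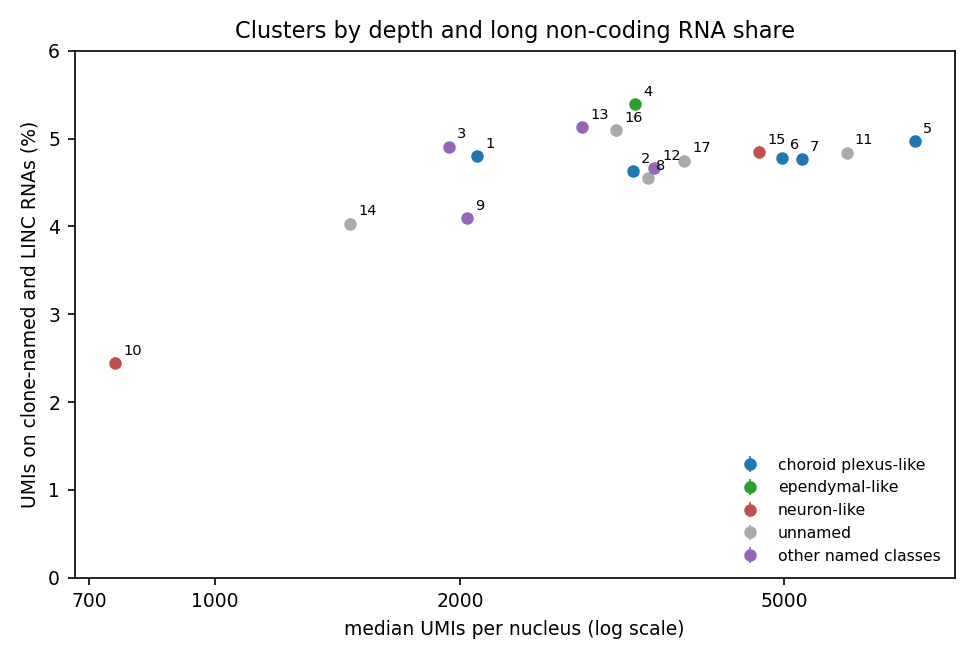
Share of UMIs on clone-named and LINC RNAs, in percent, against the median UMIs per nucleus (log scale) of the 17 clusters of both libraries; each point is a cluster with its number, and the 95% intervals for counting error are smaller than the points. Cluster 10, neuron-like, lies lowest at 2.45% with a median of 752.5 UMIs.

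Among the gene lists in neuron-like nuclei, immediate early genes, which respond within minutes to neuronal activity, were lower in the Target library. Only 3 members had enough UMIs, and their median log2 ratio was -2.93, at percentile 0 of the random lists. NPAS4 had 57 and 11 UMIs, 7.91-fold lower (4.11 to 16.7), NR4A1 had 28 and 4, 10.7-fold lower (3.74 to 41.9), and EGR1 had 23 and 14. Of the NPAS4 UMIs, 55 and 11 came from the shallow cluster, as did 27 and 2 of NR4A1 and 23 and 13 of EGR1, and whether that cluster is human is not settled. Within it NPAS4 was 2.52-fold lower in the Target library (1.31 to 5.34), NR4A1 6.81-fold lower (1.71 to 59.1) and EGR1 not lower, at 157 and 176 CPM. Synaptic adhesion genes had a median of 0.81 (percentile 100), with 17 of 23 members above 0, and medians of 0.37 with thinned nuclei, 0.43 with no filter and 1.32 with the stricter filter. GABA receptor genes had a median of 0.65 (percentile 99.9, 10 of 13 above 0; 2.03 with the stricter filter), led by GABRB2 at 4.54-fold (2.68 to 8.23) and GABBR2 at 2.45-fold, while GABRA4 was 3.22-fold lower and GABRA3 had a log2 ratio of -0.49. Axon guidance genes had a median of 0.31 (percentile 98.7, 17 of 29 above 0; -0.00581 with no filter, 0.64 at resolution 0.5 and 1.22 with the stricter filter), with UNC5C 3.46-fold and SEMA3C 3.20-fold higher and EPHA4 and UNC5A lower. Mature neuron genes had a median of 0.55 (percentile 97.9, 7 of 9 above 0), with CAMK4 2.44-fold and SYT1 2.22-fold higher, SNAP25 1.54-fold lower and ENC1 at a log2 ratio of -0.42. In synaptic adhesion the lowest members were NLGN2, with a log2 ratio of -1.31, and ADGRL1, 1.97-fold lower.

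Without the Cajal-Retzius-like cluster, a choice made after the data had been seen, the immediate early median was -1.28, the GABA receptor median -0.11 and the axon guidance median -0.18, and CNTNAP4, ADARB2 and SLC35F1, with 8 and 2, 41 and 14, and 3 and 1 UMIs, had no clear direction. Thinning to 1 depth removed most of the shallow cluster. In that setting ZBTB20, ZEB2, EPHA4, PRLR, CCNL1, VAT1L and PCAT1 had log2 ratios above 0. The mature neuron median was -0.23 there, against 1.40 with the stricter filter.

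The medians of the other lists in neuron-like nuclei lay within the central 95% of random lists. They were -0.08 for late activity-regulated genes, 0.15 for presynaptic vesicle machinery, 0.08 for glutamate receptors and postsynaptic density, 0.16 for voltage-gated ion channels and 0.43 for immature neuron genes. Upper-layer genes stood at -0.45, deep-layer genes at -0.44, cortical area patterning at -0.16, glycolysis and hypoxia at -0.04 and heat shock at -0.56. Over the alternatives upper-layer genes went from -0.90 to 0.29, deep-layer genes from -0.62 to 1.45 and area patterning from -0.28 to 1.31. The direction of these layer and area medians thus depended on the setting. Oxidative phosphorylation had 0.19, the p53 and DNA damage response -0.54, neurotrophin and growth factor signalling 0.04, and astrocyte transport and homeostasis -0.49. Extracellular matrix and perineuronal net genes had -0.04 and calcium-dependent transcription regulators -0.41. The unfolded protein list had 2 members with enough UMIs and the reactive astrocyte list 1, so neither has a value.

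In choroid plexus-like nuclei, with 6080309 Non-Target and 13809406 Target UMIs, heat shock genes were lower in the Target library, and RGS2, a regulator of G-protein signalling, was the lowest named gene. The Non-Target class came mostly from clusters 2 and 6 (707 and 433 nuclei) and the Target class from clusters 1 and 5 (886 and 601 nuclei). RGS2 (chromosome 1, 192809039 to 192812283) was at 33.9 CPM (29.4 to 38.8) and 8.11 CPM (6.68 to 9.76), 4.18-fold lower (3.30 to 5.31). INSC, ATOH8, PCSK2 and LINGO1 were between 3.42-fold and 3.90-fold lower. COL3A1, a fibrillar collagen of fibroblasts (chromosome 2, 188974320 to 189012746), had 8 and 603 UMIs, 33.2-fold higher (16.7 to 77.2), and its 43.7 CPM in the Target class was 1.81% of its level in Target fibroblast-like nuclei. Free RNA from those nuclei, or doublets still present, stays open as the source of the COL3A1 difference. FAR2, a fatty acyl-CoA reductase gene, was 7.12-fold higher (3.15 to 19.9), CA8 5.86-fold, LUZP2 4.95-fold and RASSF6 4.88-fold.

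The heat shock median in choroid plexus-like nuclei was -0.57 (percentile 0.03), with 8 of 10 members below 0. DNAJB1 was 1.91-fold lower (1.32 to 2.75) and HSPH1 1.74-fold lower (1.54 to 1.95), while HSPE1 had a log2 ratio of 0.01 and HSPA1B, whose reads are uncertain because of its near-identical copy HSPA1A, 0.29. Immediate early genes had a median of -0.65 (percentile 0.06, 8 of 10 below 0), with NPAS4 4.34-fold and EGR1 2.27-fold lower, and BTG2 and JUNB at log2 ratios of 0.71 and 0.50. Per cluster the immediate early median lay within the random lists, at -0.43 in cluster 1, -0.75 in cluster 2, 0.39 in cluster 5 and 0.08 in cluster 6, and cluster 7 had too few members. GABA receptor genes had -0.57 (percentile 0.13, 9 of 9 below 0), with GABRB1 and GPHN nearest 0 at -0.15 and -0.03, and -0.19 with members of at least 100 UMIs and -0.21 with doublet calls kept or with scaling within each library. Synaptic adhesion genes had 0.24 (percentile 99.99, 16 of 25 above 0), with LRRTM3 4.56-fold and TENM3 2.37-fold higher and CNTNAP4 and ADGRL1 1.73-fold and 1.53-fold lower. That median was near 0 with equal weight for the 5 clusters, at 0.0122, and 0.0360 and 0.0820 with seeds 4 and 5.

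Reactive astrocyte genes had a median of 0.57 in choroid plexus-like nuclei (percentile 99.8, 8 of 13 above 0), where S100A10 had 1 and 41 UMIs, a ratio of 18.1 (3.06 to 730), and SERPINA3 was 4.97-fold higher, with STAT3 and HSPB1 at -0.33 and -0.27. Extracellular matrix and perineuronal net genes had 0.49 (percentile 99.7, 8 of 11 above 0), with NCAN at 2 and 23 UMIs and TNC 3.67-fold higher, and SPOCK3 and RELN at -0.62 and -0.43. That matrix median was -0.13 with equal weight for the 5 clusters, an alternative chosen after the data had been seen, and both medians came near 0 when nuclei were thinned, at 0.01 and 0.05. Fibroblast-like and astroglia-like nuclei were mostly in the Target library. Free RNA from them, or doublets still present, stays open as a source for both lists. The immediate early median was -0.195 with all barcodes kept, -0.11 with thinned nuclei and -0.14 with the stricter filter.

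The other lists in choroid plexus-like nuclei lay within the central 95% of random lists. Late activity-regulated genes stood at -0.14, presynaptic vesicle machinery at -0.21, glutamate receptors at -0.11, voltage-gated ion channels at -0.11 and axon guidance at -0.10. Immature neuron genes had 0.39, mature neuron genes 0.05, upper-layer genes -0.08, deep-layer genes 0.05 and cortical area patterning -0.22. Glycolysis and hypoxia had -0.06, the unfolded protein response -0.11, oxidative phosphorylation 0.07 and the p53 response -0.17. Neurotrophin signalling had -0.08, astrocyte transport 0.11 and calcium-dependent regulators 0.08.

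Ependymal-like nuclei, all from cluster 4, held 464466 Non-Target and 2455921 Target UMIs. The interferon-induced genes IFI44L and IFI6 were among the highest in the Target library. IFI44L (chromosome 1, 78619922 to 78646145) had 3 and 129 UMIs, a ratio of 8.13 (2.72 to 39.9), and IFI6 had 3 and 113, a ratio of 7.12 (2.38 to 35.1). COL3A1 had 0 and 139 UMIs, 8.76-fold higher with the 0 set at the floor of 3 UMIs, and its exact interval began at 7.03. Free RNA from fibroblast-like nuclei, or doublets still present, stays open as its source here too. ZNF804B was 7.68-fold (3.24 to 23.9) and PLAC9 6.38-fold higher. DGKG, a diacylglycerol kinase gene, was 3.58-fold lower (2.36 to 5.39), ENOX1 3.07-fold, RASEF 3.01-fold, SHISA9 2.86-fold and LENG9 2.85-fold. Over the alternatives the log2 ratio of IFI44L went from 0.56, with the stricter filter, to 2.86, and that of IFI6 from 1.10 to 3.21. The log2 ratio of ZNF804B was -0.11 with the stricter filter and -0.33 with scaling within each library.

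Heat shock genes in ependymal-like nuclei had a median of -0.48 (percentile 0.87, 7 of 8 below 0), with HSPH1 2.02-fold lower (1.45 to 2.77) and HSPA8 at -0.70, BAG3 at -0.08 and HSPB1 at 0.31. Glutamate receptor and postsynaptic density genes had -0.33 (percentile 1.04, 14 of 19 below 0), with DLGAP1 2.51-fold lower, GRM5 at -1.04, GRIK2 2.57-fold higher and GRIN2A at 1 and 29 UMIs. Synaptic adhesion genes had 0.21 (percentile 99.6, 15 of 21 above 0), with LRRTM4 2.64-fold (1.98 to 3.59) and LRRTM3 3.22-fold higher, ADGRL1 1.71-fold lower and NLGN2 at -0.95. Immature neuron genes had 0.59 (percentile 98.2, 5 of 6 above 0), with DCX at 2 and 36 UMIs, NCAM1 at 0.91, SOX4 at 0.04 and CD24 at -0.97. Mature neuron genes had 0.55 (percentile 99.6) from 3 members, MAP2, CHN1 and SYT1, at 0.85, 0.55 and 0.36. The synaptic adhesion and immature neuron medians were -0.04 and -0.22 with the stricter filter.

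The other lists in ependymal-like nuclei lay within the central 95% of random lists. Immediate early genes had 0.34, late activity-regulated genes 0.09, presynaptic machinery 0.00, GABA receptors -0.25, voltage-gated channels 0.00 and axon guidance 0.20. Upper-layer genes had -0.05, deep-layer genes -0.08, cortical area patterning -0.48, glycolysis and hypoxia -0.15 and the unfolded protein response 0.02. Oxidative phosphorylation had 0.09, the p53 response -0.32, neurotrophin signalling 0.09, astrocyte transport 0.25, reactive astrocyte genes 0.65, matrix genes 0.20 and calcium-dependent regulators 0.08.

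**Figure D3:**
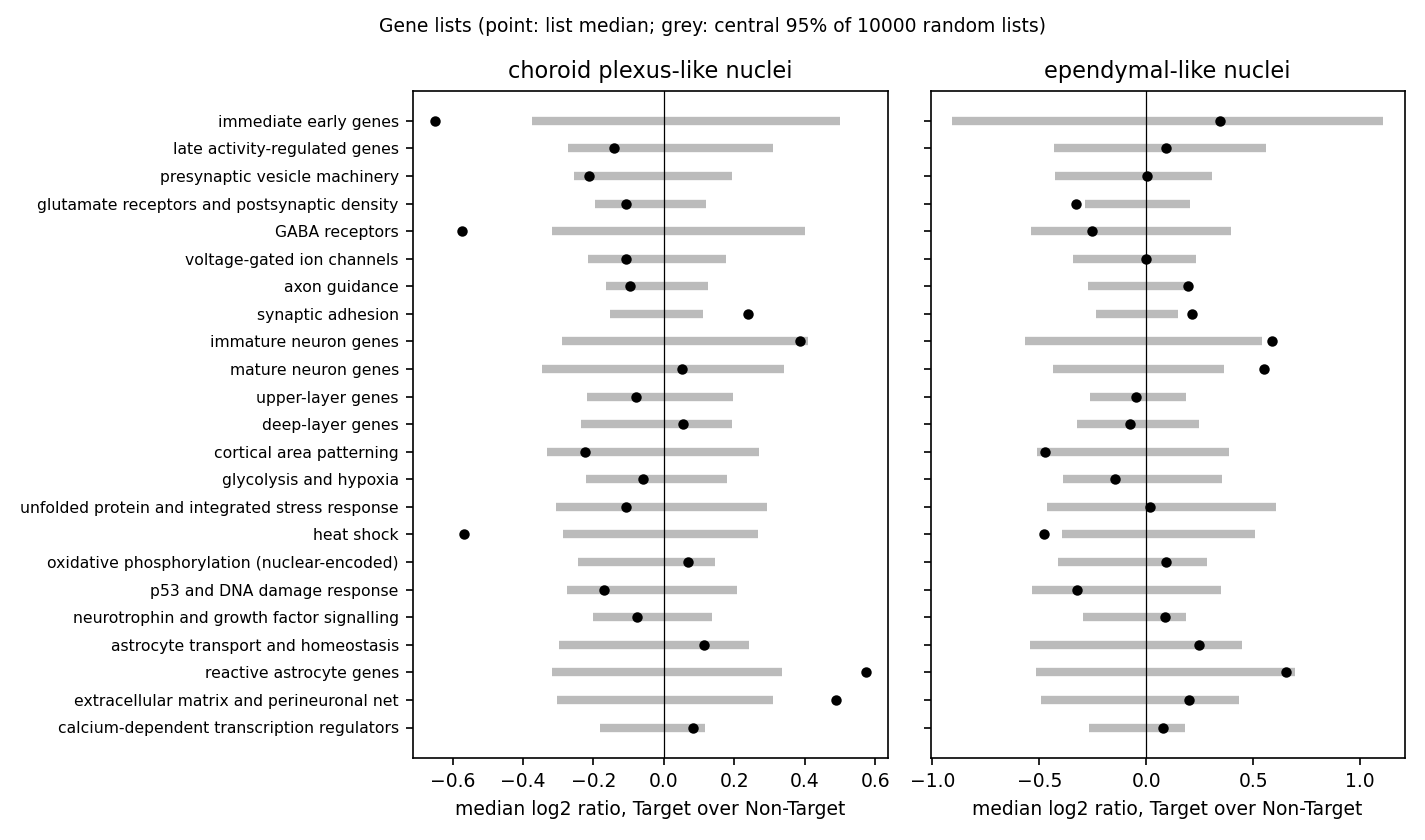
Median log2 ratio, Target over Non-Target, of each gene list in choroid plexus-like (left) and ependymal-like (right) nuclei, 1 library per group; points are list medians and grey bars the central 95% of 10000 random lists matched on expression. Heat shock genes lay below the grey bar in both classes, at -0.57 and -0.48.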

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

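The test on zinc finger genes was planned before its value was seen, and the tests on non-coding RNAs and on SNAP25 were chosen after. Barcodes outside the filter, used in no setting but the one without a filter, carried neuronal RNA above the level that a count of 0 allows. SNAP25 was at 248 CPM in the 428 Non-Target barcodes outside the filter and at 71.6 CPM in the 977 Target ones, against 47.0 and 24.5 CPM in the analysed nuclei. GRIA2 was at 1772 and 557 CPM, against 329 and 151 CPM in the analysed nuclei. TTR was also higher outside the filter, at 21972 and 20109 CPM.

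A related pattern is the shallow neuron-like cluster, whose leading genes are neuronal genes shared by human and mouse. Clone-named and LINC RNAs were 2.45% of UMIs (2.38 to 2.51), below the 4.03% to 5.39% of the other clusters, which argues against human neurons sampled at low depth. Zinc finger genes, poorly conserved between the species, were 1.15% of UMIs (1.10 to 1.19) against 1.35% to 1.65%, so host mouse neurons whose RNA maps in part to human genes may be the source. Droplets with free RNA and no nucleus stay open, since SNAP25, 62.7-fold above all other nuclei (54.5 to 72.0), is among the genes that lead the cluster and cannot decide. Damaged human nuclei were not tested and stay open, and no biological explanation was tested. An unnamed cluster of 200 Non-Target and 126 Target nuclei (median 3402.5 UMIs) shared leading genes with the shallow cluster, among them GRIA2, SNAP25, CAMKV and BCL11A. That unnamed cluster kept choroid plexus markers. Its clone-named and LINC RNAs were 4.55% and its zinc finger genes 1.41% of UMIs. How the 2 clusters relate was not tested.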

How the results depend on the processing

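Most alternatives were planned; the tests with doublet scores removed, with equal cluster weights, without the Cajal-Retzius-like cluster, and on the joint share of choroid plexus-like and unnamed clusters that keep choroid plexus markers were chosen after the data had been seen. No paired analysis was possible because each group has 1 library. Over all alternatives the log2 ratios of named genes reversed 13 times, moved outside their main interval 125 times and stayed within it 643 times. The 16 list medians outside the random range reversed 8 times, moved 26 times by more than the spread of the random lists to one side of its centre, and stayed 262 times, and share differences reversed 2 times, moved 47 times and stayed 77 times. The list medians within the random range moved 53 times and stayed 865 times. The heat shock median in choroid plexus-like nuclei never moved. The planned layer alternatives (a lower thinning depth, no thinning, no filter) were not run, because no cluster met the excitatory rule in the main setting, although the shallow neuron-like cluster did in 4 alternatives. The name clusters with choroid plexus markers stands for the choroid plexus-like and unnamed ones. Values below are share differences in percentage points, Target minus Non-Target, or log2 values, and the cause was not tested except where the setting itself leaves out nuclei. Depth limits which genes can be summarised, with 3 immediate early genes at the list minimum in neuron-like and in ependymal-like nuclei.

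Without the filter the differences were 14.2 for fibroblast-like, 1.37 for cycling-cell-like and -2.66 for unnamed nuclei, and -24.2 for clusters with choroid plexus markers. Median UMIs were 2606 and 3128 and median genes 1602 and 1773. In neuron-like nuclei axon guidance had -0.00581 and synaptic adhesion 0.43, and in choroid plexus-like nuclei immediate early genes had -0.195.

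With the stricter filter the differences were -8.22 for choroid plexus-like, 7.16 for ependymal-like, -7.37 for neuron-like, 11.04 for fibroblast-like, 3.57 for OPC-like, 3.04 for cycling-cell-like and -12.8 for unnamed nuclei, and -23.0 for clusters with choroid plexus markers. In neuron-like nuclei GABA receptors had 2.03, axon guidance 1.22, synaptic adhesion 1.32 and mature neuron genes 1.40. Immediate early genes in choroid plexus-like nuclei had -0.14. In ependymal-like nuclei ZNF804B had -0.11, synaptic adhesion -0.0401 and immature neuron genes -0.22.

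With doublet calls kept the differences were -1.50 for choroid plexus-like, 3.28 for OPC-like and -26.7 for unnamed nuclei, and -25.1 for clusters with choroid plexus markers, and GABA receptors in choroid plexus-like nuclei had -0.21. At resolution 0.5 they were -8.01 for neuron-like and -1.57 for unnamed nuclei and -22.5 for clusters with choroid plexus markers, and axon guidance in neuron-like nuclei had 0.64. At resolution 2 they were -18.0 for choroid plexus-like, 3.69 for ependymal-like and 2.73 for OPC-like nuclei.

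With 4000 variable genes the differences were -15.9 for choroid plexus-like, 6.37 for ependymal-like, 3.16 for OPC-like and -13.4 for unnamed nuclei, and -24.9 for clusters with choroid plexus markers. PRLR in neuron-like nuclei had 0.25, synaptic adhesion in choroid plexus-like nuclei 0.42 and immature neuron genes in ependymal-like nuclei 0.00525. With scaling within each library the differences were -23.1 for choroid plexus-like, 8.87 for ependymal-like, 14.8 for fibroblast-like and 3.06 for OPC-like nuclei, and -31.0 for clusters with choroid plexus markers. GABA receptors in choroid plexus-like nuclei had -0.21 and ZNF804B in ependymal-like nuclei -0.33.

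With seed 3 the differences were -12.2 for choroid plexus-like, 7.19 for ependymal-like and -17.5 for unnamed nuclei, and -30.9 for clusters with choroid plexus markers. With seed 4 they were 5.15, 7.24, -34.7 and -30.7, as nuclei passed from choroid plexus-like to unnamed clusters. Synaptic adhesion and matrix genes in choroid plexus-like nuclei then had 0.0360 and 0.14, and mature neuron genes in ependymal-like nuclei 1.04. With seed 5 the differences were -8.89 for choroid plexus-like and -18.7 for unnamed nuclei, and synaptic adhesion in choroid plexus-like nuclei had 0.0820.

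With thinned nuclei the differences were 7.04 for ependymal-like, 0.0101 for neuron-like and 10.9 for fibroblast-like nuclei. In neuron-like nuclei PCAT1 had 0.66, ZBTB20 0.31, PRLR 0.75, EPHA4 1.14, CCNL1 2.28, ZEB2 1.36, VAT1L 0.75, synaptic adhesion 0.37 and mature neuron genes -0.23, after thinning had removed most of the shallow cluster. In choroid plexus-like nuclei immediate early genes had -0.11, reactive astrocyte genes 0.0139 and matrix genes 0.0454.

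With the highest doublet scores removed the differences were -15.0 for choroid plexus-like, 11.4 for fibroblast-like and -8.80 for unnamed nuclei, and -23.3 for clusters with choroid plexus markers. Synaptic adhesion in choroid plexus-like nuclei had 0.39 and immature neuron genes in ependymal-like nuclei -0.0498. With members of at least 100 UMIs, GABA receptors, reactive astrocyte and matrix genes in choroid plexus-like nuclei had -0.19, 0.0780 and 0.0110. With equal weight for each cluster synaptic adhesion had 0.0122 and matrix genes -0.13. Without the Cajal-Retzius-like cluster CNTNAP4 had -0.78, ADARB2 -0.53 and SLC35F1 -0.23, each with an interval that spans 0, and immediate early genes had -1.28, GABA receptors -0.11 and axon guidance -0.18.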

Other observations

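The tests on depth, hidden fibroblasts, free RNA and cluster mix were written before their values were seen, whereas the comparison of hidden fibroblasts with the whole difference, the quotient against DCN, the interferon list, its median without the genes that prompted it and its values per cluster were chosen after the data had been seen. Interferon response genes, which cells switch on after interferon signalling, were higher in Target choroid plexus-like nuclei. Of 31 members with enough UMIs 27 had a log2 ratio above 0, and the median was 0.66 (percentile 100). IFI44L was 3.85-fold higher (2.80 to 5.41), IFI6 3.71-fold (2.74 to 5.11), EPSTI1 3.23-fold (2.14 to 5.08) and B2M, the light chain of MHC class I, 2.86-fold (2.32 to 3.55). STAT2, IRF7, TRIM22 and SAMD9L were not higher. Without IFI6, IFI44L and B2M the median was 0.58 (percentile 100), and in ependymal-like nuclei the median was 1.41 with them and 1.02 without.

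The interferon median was above 0 in each choroid plexus-like cluster, from 0.30 in cluster 2 to 0.77 in cluster 7. Heat shock genes had medians below 0 in the same 5 clusters, from -0.28 in cluster 7 to -0.78 in cluster 2, and lay outside the random lists in clusters 2 and 6 and within them in clusters 1, 5 and 7.

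For the interferon pattern, free RNA from fibroblast-like nuclei would bring COL3A1 in the same ratio, but the choroid plexus-like over fibroblast-like quotient of IFI6 and IFI44L was 46.3 times that of COL3A1, and 11.05 times that of DCN, the highest of 5 fibroblast genes. A different mix of choroid plexus-like clusters is argued against by the median of 0.84 with equal weight for each cluster. Free RNA from other cells was not tested, and it stays open for IFI6, which was at 29.3 CPM in Target choroid plexus-like, 35.4 CPM in neuron-like and 33.2 CPM in OPC-like nuclei. IFI44L was at 27.2, 2.72 and 4.74 CPM there. Whether this follows neuromodulation stays open with 1 library per group.

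Fibroblast-like, OPC-like and astroglia-like nuclei were mostly in the Target library. Deeper sequencing of that library is argued against as the whole cause for fibroblast-like nuclei, since their share difference was 10.9 percentage points (9.95 to 11.9) after thinning to 1 depth, against 15.9. Fibroblast nuclei hidden in other Non-Target clusters are argued against as the whole cause among nuclei thinned to 1700 UMIs. Outside the class, 34 of 1775 such Non-Target nuclei (1.92%, 1.33 to 2.67) held at least 2 fibroblast genes. The value was 315 of 3544 (8.89%) in the Target library, and its cause was not tested. The Non-Target upper bound, raised to 2.81% for nuclei that this rule misses, lies below 9.95. The 588 Non-Target nuclei with fewer UMIs were not examined. Some hidden nuclei stay open, as the interval crosses the bound of 2% set beforehand. Which graft or part of a graft went into each library cannot be told apart from neuromodulation with 1 library per group.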
